A study of Equus caballus with 34 samples.

How the data were processed

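Endometrial biopsies of subfertile mares were profiled by 3′ mRNA sequencing, in 17 libraries made before and 17 made after intrauterine treatment with a vesicle preparation that the submitters call AMC-EVs. Per the labels' protocols, RNA was extracted from tissue kept in RNAlater, libraries were made with the QuantSeq 3′ FWD kit, which yields 1 fragment per transcript from its 3′ end, and only the first read of each pair was used. Each deposited file held the whole-number read counts of 1 library for 38849 Ensembl horse gene IDs, followed by 5 HTSeq summary classes. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.5c and HTSeq 1.99.2 and the horse build EquCab3.0. The annotation release, the strand setting, the trimming and any use of molecular identifiers are not given in the sources used here. Because the kit reads 3′ ends, counts did not depend on transcript length, but a read in a 3′ end that the annotation lacked fell outside every gene.

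The summary classes were left out of library sizes and tests. Reads outside annotated genes made up 15.9% to 28.9% of the aligned reads in a file, reads on overlapping genes 7.75% to 11.6%, and reads with more than 1 alignment 6.71% to 12.9%. The classes for low alignment quality and unaligned reads were listed at 0 in all 34 files. Counts in genes ranged from 3194874 to 9583399 per library. No pair among the 272 within-group library pairs was close to sampling noise, since the smallest chi-square per gene was 15.4. Pairs across the groups were not checked in this way. All 34 were treated as separate samples.

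The files pair no gene ID with a symbol, and 0 of the 38849 IDs matched the RefSeq gene table used here. The 30 gene lists, the 8 marker genes and the rule for named genes fixed before the data were examined all need symbols, so none of them was analysed here. Coordinates and annotations of the IDs are not given for the same reason. In place of the named genes, the 2 IDs with the smallest p in each direction are given. The abundance classes were set after the data were examined.

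Groups came from the treatment label. The series text describes paired comparisons, but the labels number the libraries 1 to 17 before and 18 to 34 after treatment and do not tie them to mares, so the groups were compared unpaired. Genes were filtered with filterByExpr, which left 12613, normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called changed. Log2 CPM values used a prior count of 2. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The whole-transcriptome difference was tested by PERMANOVA on Euclidean distances of log2 CPM and the spread by the distance of each library to its group centroid. These tests and the tests of library measures were two-sided permutation tests (one-sided for PERMANOVA) with 100000 resamples in NumPy 2.4.6 and SciPy 1.17.1, whose smallest possible p is 1e-05. The 11 tests of library measures were adjusted together by the Benjamini-Hochberg method. Detected genes were counted after each library had been thinned at random to 3194874 counts, and a gene counted as detected with at least 1 count.

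The fit was tested on simulated data with the means, dispersions and library sizes of this comparison over 12613 genes, 200 of them changed. It recovered 6% of the genes changed 1.25-fold, 46% of those changed 1.5-fold, 70% of those changed 2-fold and 86% of those changed 3-fold. Of its calls 0.952% were unchanged genes, and it called 0 genes when none was changed. Each gene was drawn independently, without differences in composition shared by many genes, and far fewer genes were changed than the 3507 called in the data. These rates therefore do not carry over to the data.

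Alternatives were other normalisations, DESeq2 1.42.0, limma 3.58.1 with sample quality weights, other low-count filters, library size as covariate, thinned counts, 2 surrogate variables (sva 3.50.0), removal of the 20 most abundant genes, an assumed pairing of library n with library n+17, and leaving out each library in turn. The share of reads outside genes as covariate and the removal of the post-treatment libraries 18 to 24 or 25 to 34 were added after seeing the data. For the fit with that covariate, the residual of the group on the share was shuffled in 99 draws, counted together with the real one. With the assumed pair block added, its sign was switched within pairs in 29 draws. For the spread in parts of the treated group, distances were multiplied by the square root of n/(n-1). Intervals and p-values cover the spread between these libraries, which the labels describe only by number.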

Results

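The study followed 17 subfertile mares over 6 successive cycles and asked how the endometrial transcriptome differed after vesicle treatment. The endometrium is the mucosal lining of the uterus. A first biopsy was taken in cycle 1 and a second in cycle 5. In between, during cycles 3 and 4, AMC-EVs were given into the uterus, with 2 administrations and a stated amount of 20 × 10⁹ vesicles. The data hold 17 libraries from before and 17 from after treatment and no untreated mares. Cycles 2 and 6 are recorded as embryo cycles, and cycle 2 also lay between the biopsies. Time, treatment, repeated uterine sampling and the embryo cycle therefore differ together between the groups. Whether the libraries of the 2 groups were made and sequenced together is not known here, so handling may differ along with them. Reads counted in genes were 6089710 ± 743473 before treatment and 5289190 ± 1727940 after it (SD, n = 17 each), a difference that did not pass the test (adjusted p = 0.107, permutation test). Aligned reads of all classes were 10795900 ± 1117990 before and 8591090 ± 2892170 after treatment (SD, n = 17 each), a lower mean that was not tested. Depth was uneven after treatment. The libraries numbered 18 to 24 held 5901887 to 9583399 counts and those numbered 25 to 34 held 3194874 to 4936728. The mean of libraries 18 to 24 alone, 7032310, was above that from before treatment (adjusted p = 0.0372, permutation test). Of all 17 libraries from after treatment, 9 lay below every library from before it.

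The first comparison asked whether endometrial biopsies differed as a whole between the 2 time points. They did, and biopsies taken after treatment also differed more from one another, a spread that was larger in libraries 25 to 34. The group accounted for 12.8% of the variance of log2 CPM over the 12613 tested genes (permutation test on distances between libraries, p = 1e-05, the smallest the resamples can give). The mean distance of a library to its group centroid was 60.9 ± 6.68 before and 82.2 ± 13.99 after treatment (SD, n = 17 each, log2 CPM units), a difference of 21.3 with a permutation p of 1e-05. Without libraries 25 to 34 the difference was 5.78 and did not pass the test (68.6 ± 6.89, n = 7, against 62.8 ± 6.88, n = 17, SD, permutation p = 0.0757), and without libraries 18 to 24 it was 31.3 (94.1 ± 10.25, n = 10, SD, permutation p = 1e-05), with distances corrected for unequal group size. At equal depth these 2 differences were 4.65 (permutation p = 0.104) and 22.7 (permutation p = 1e-05). Unequal spread enters the test of the whole transcriptome too, which therefore does not describe a shift of centroids alone. The first principal component carried 20.6% of the variance, and 14 of the 17 libraries from after treatment lay beyond all 17 from before it. Without libraries 25 to 34 the group accounted for 10.49% of the variance (permutation p = 0.00043).

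**Figure D1:**
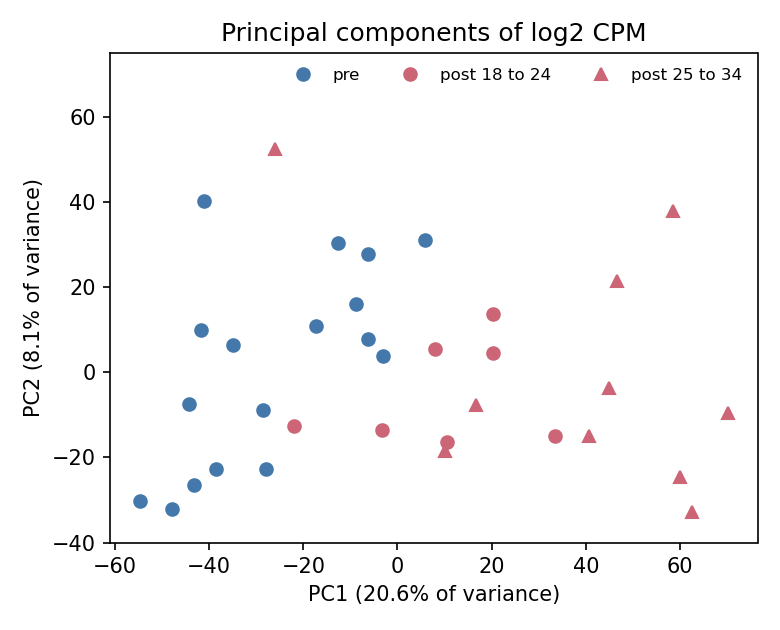
Principal components of log2 CPM for the 34 libraries, with the component scores on both axes, circles for libraries before treatment and for libraries 18 to 24 after it, and triangles for libraries 25 to 34. Along the first axis, 14 libraries from after treatment lie beyond all libraries from before it and the other 3 among them.

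The second comparison asked which genes changed after treatment. Of the 12613 genes tested, 3507 (27.8%) were called changed, 1822 of them higher and 1685 lower after treatment (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Most changes were small. The median absolute log2 fold change of the called genes was 0.55, with a median standard error of 0.14. Changes of at least 2-fold were more often decreases, with 340 genes lower and 132 higher. In no gene did all 17 libraries of one group lie beyond all 17 of the other. The share of reads outside annotated genes, described further on, moved with the groups. With that share as a covariate, a setting chosen after seeing the data, 66 genes were called. With a block for assumed pairs of libraries n and n+17 added, 3 were called. Without libraries 25 to 34, which leaves 7 libraries from after treatment, 890 genes were called, 406 higher and 484 lower. In that fit the genes called over all libraries had a median absolute log2 fold change of 0.42 with a median standard error of 0.17.

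Called genes were divided by abundance, since the balance of increases and decreases varied along it. Among the 2253 genes with a mean below 5 CPM, 68 rose and 193 fell, and 163 of those that fell did so by at least 2-fold. Among the 3991 genes from 5 to 20 CPM, 383 rose and 470 fell. The 4742 genes from 20 to 100 CPM had 923 that rose and 775 that fell, a balance that upper-quartile scaling turned to 832 and 867. Above this, increases were in the majority, with 388 against 223 of the 1411 genes from 100 to 500 CPM and 60 against 24 of the 216 genes at 500 CPM or more, and this majority held with upper-quartile scaling (351 against 260 and 53 against 24). Genes that rose had a median of 44.4 CPM, genes that fell 27.1 CPM and all tested genes 20.4 CPM. The single most abundant gene of the data set, looked up after the values were seen, fell from 46892 ± 17253 to 20241 ± 12309 CPM (SD, n = 17 each), a log2 fold change of -1.21 with a standard error of 0.24 (edgeR adjusted p = 0.000442), and was below the median from before treatment in 16 of 17 libraries. It took 0.582% to 7.55% of the counts of a library. With the share of reads outside genes as a covariate its log2 fold change was -0.051 (edgeR adjusted p = 0.96). Low-count genes also need larger folds to be called, so these shares are not shares of genes that truly differed.

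**Figure D2:**
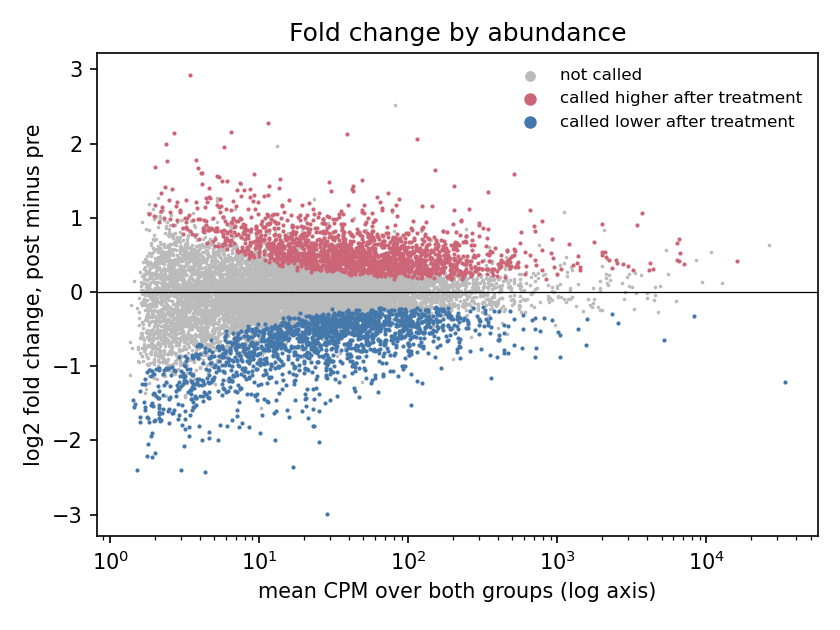
Log2 fold change after against before treatment (vertical axis) by mean CPM over both groups (horizontal log axis) for the 12613 tested genes, with called genes in colour. Of the genes called by at least 2-fold, 340 lie below zero and 132 above it, and 163 of the 340 have a mean below 5 CPM.

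The largest test statistics belonged to moderately and highly abundant genes. ENSECAG00000006905 rose from 23.2 ± 8.0 to 62.4 ± 21.2 CPM (SD, n = 17 each), a log2 fold change of 1.43 with a standard error of 0.17 (edgeR adjusted p = 2.81e-06). It was above the median from before treatment in 16 of 17 libraries. ENSECAG00000027681, an abundant transcript, rose from 2369 ± 448 to 4446 ± 1066 CPM, a log2 fold change of 0.91 ± 0.11 (SE, edgeR adjusted p = 2.81e-06), and lay above that median in 16 of 17. ENSECAG00000014982 decreased from 67.7 ± 17.4 to 33.2 ± 9.12 CPM, a log2 fold change of -1.02 ± 0.13 (SE, edgeR adjusted p = 2.81e-06). ENSECAG00000042692 decreased from 924 ± 258 to 502 ± 129 CPM, a log2 fold change of -0.88 ± 0.12 (SE, edgeR adjusted p = 8.99e-06). The genes that decreased were below the median from before treatment in all 17 libraries. With the share of reads outside genes as a covariate, the log2 fold change was 0.83 for ENSECAG00000006905 (edgeR adjusted p = 0.0976), 0.79 for ENSECAG00000027681 (edgeR adjusted p = 0.0359), -0.77 for ENSECAG00000014982 (edgeR adjusted p = 0.0483) and -0.61 for ENSECAG00000042692 (edgeR adjusted p = 0.0975). With a block for assumed pairs of libraries n and n+17 added, it was 1.18, 0.64, -0.87 and -0.73 in the same order, and none of the 4 was called (edgeR adjusted p = 0.128, 0.227, 0.13 and 0.147).

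**Figure D3:**
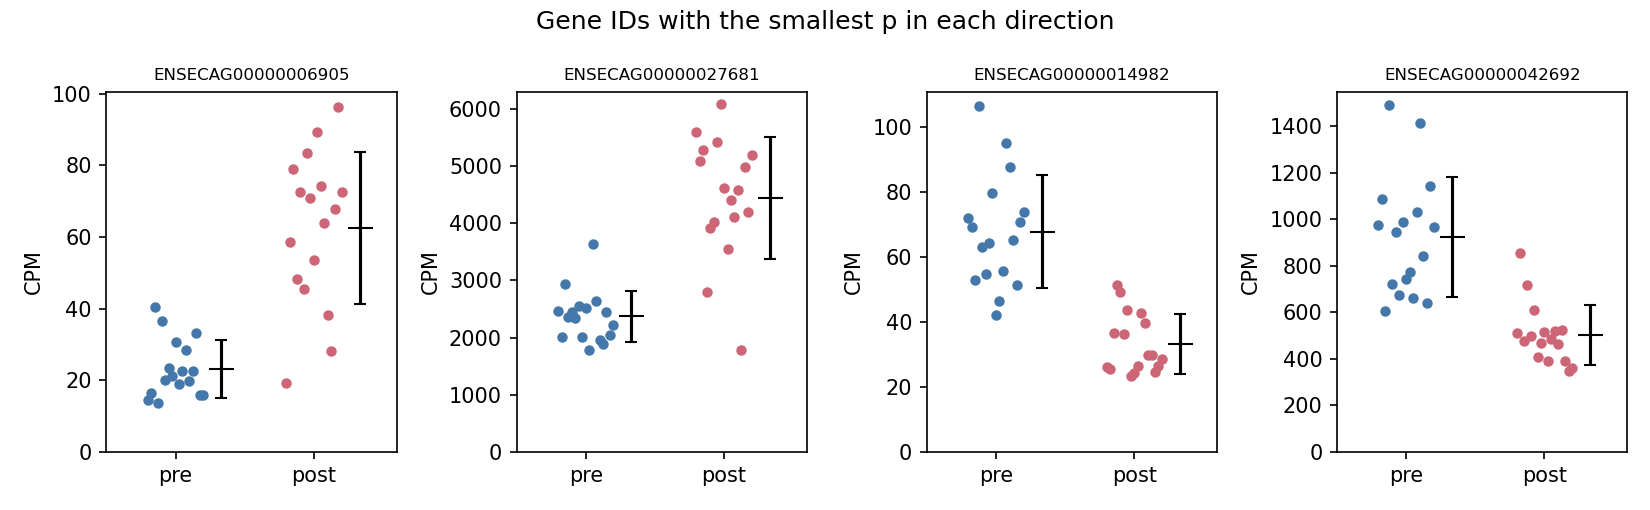
CPM per library (points) with mean and SD (black) for the 2 gene IDs with the smallest p in each direction, before and after treatment, n = 17 each. The IDs ENSECAG00000006905 and ENSECAG00000027681 are higher after treatment and ENSECAG00000014982 and ENSECAG00000042692 lower, with overlap between groups in all 4.

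Within the group sampled after treatment, the libraries of unequal depth were compared with one another and with the group from before treatment. Libraries 25 to 34 against the 17 from before treatment gave 3621 called genes, 1870 higher and 1751 lower (edgeR, adjusted p below 0.05), and 4199 in DESeq2. Libraries 18 to 24 gave 890 in edgeR and 1434 in DESeq2. Libraries 25 to 34 against libraries 18 to 24 gave 0 called genes in edgeR, with 945 genes at an unadjusted p below 0.05 where chance gives 605, and 38 called genes in DESeq2. The 2 larger counts come from unequal numbers of libraries (10 and 7) and share their controls, so the counts alone do not measure a difference in response. The genes called over all libraries had a median absolute log2 fold change of 0.65 in libraries 25 to 34 and 0.42 in libraries 18 to 24. The median standard error was 0.17 in both fits. Those genes were called with libraries 25 to 34 as the larger part of the group, which favours larger folds there, and this difference in fold was not tested.

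The third comparison concerned the make-up of the libraries. After treatment fewer genes were detected and fewer reads fell outside annotated genes. At an equal depth of 3194874 counts, 16698 ± 418 genes were detected before and 14861 ± 855 after treatment (SD, n = 17 each), a difference of -1837 with a standard error of 231 (adjusted p = 2.2e-05, permutation test). In 14 of 17 libraries from after treatment the number was below every library from before it. Reads outside annotated genes fell from 25.3% ± 1.79 to 20.1% ± 2.704 of aligned reads (adjusted p = 2.2e-05, permutation test), and 13 of 17 libraries were below every library from before treatment. Reads in genes rose from 56.3% ± 2.60 to 61.8% ± 2.79 (adjusted p = 2.2e-05, permutation test). Both are shares of the same total, so this rise is not separate from the fall outside genes. Genes too low for testing together held 0.436% ± 0.0646 of gene counts before and 0.341% ± 0.0629 after treatment (adjusted p = 0.000283, permutation test). The share of the 20 most abundant genes was 20.2% ± 1.95 before and 20.6% ± 1.61 after treatment and was not called different (difference 0.426 with a standard error of 0.612, adjusted p = 0.491, permutation test). Libraries 18 to 24 alone had a higher mean depth than the libraries from before treatment. In them 15511 ± 492 genes were detected at equal depth and 21.4% ± 2.39 of reads lay outside genes (SD, n = 7). Both remained below the values from before treatment (adjusted p = 0.000165 and 0.00055, permutation tests). Reads with more than 1 alignment fell from 9.41% ± 1.84 to 7.88% ± 1.02 over all libraries (SD, adjusted p = 0.00694, permutation test). In libraries 18 to 24 alone they were 8.29% ± 1.07 and did not pass the test (adjusted p = 0.185, permutation test).

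**Figure D4:**
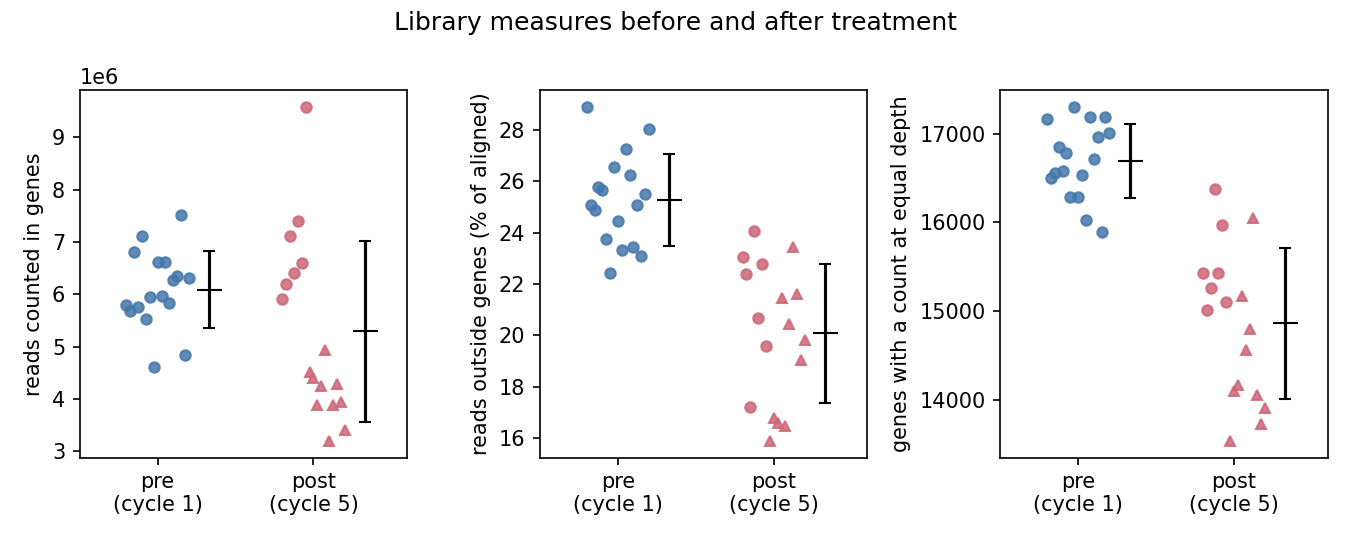
Reads counted in genes, reads outside annotated genes (percent of aligned reads) and genes with a count at equal depth, per library, before (cycle 1) and after (cycle 5) treatment, with triangles for libraries 25 to 34 and mean and SD in black. The vertical axes do not start at zero, and the last 2 measures are lower after treatment (20.1% against 25.3%, and 14861 against 16698 genes).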

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

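The fits with the share of reads outside genes as covariate, with and without a pair block, and their draws were chosen after the results were seen, as were the bounds by which the 2 tests of depth were read. A measure outside the gene counts was higher after treatment than before. Reads on overlapping genes, which HTSeq assigns to no gene, made up 10.2% ± 0.828 of aligned reads after and 8.98% ± 0.628 before treatment (SD, n = 17 each, adjusted p = 7.33e-05, permutation test), and 8 of 17 libraries lay above every library from before treatment. All read classes are shares of the same total, so the fall in reads outside genes raises this share by itself. A rise beyond that was not tested.

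The first pattern is the set of 3507 genes called between the groups. Chance is argued against as its source. Of 100 splits of the 34 libraries into 17 and 17, all drawn at random but the real one, 1 (the real one) called as many genes. This is the smallest share that 100 splits can give, and the splits did not keep any pairing by mare. The highest of the random ones called 11. A difference in depth as the whole cause is argued against, since 87.8% of the called genes were called in the same direction after thinning every library to the smallest total. Library composition, tracked by the share of reads outside genes, is harder to set apart, because the group explains 57.7% of the variance of that share. A split that put the 17 libraries with the smallest share on one side (15 from after and 2 from before treatment) called 4206 genes, more than the real split. A split by the 17 smallest gene counts (10 from after and 7 from before treatment) called 0. A linear trend with the share as measured as the whole cause is argued against. With the share as covariate 66 genes were called, and of 100 draws of the group shuffled after removal of its part that follows the share, 1 (the real one) called as many, the highest of the others 38. Over the 3507 genes the median log2 fold change in the original direction went from 0.55 to 0.251 with the covariate while the median standard error grew from 0.14 to 0.21, and 46 stayed called. With a block for assumed pairs n and n+17 added, the values were 0.30 and 0.26 and 2 of the 3507 stayed called, so the fold did not shrink further and the standard error grew. That fit called 3 genes in all, and of 30 draws with the sign of what remains of the group switched at random within pairs, 1 (the real one) called as many, the highest of the others 0. With pairs the evidence against the trend thus rests on 3 genes. A part of composition that the share does not follow linearly, or follows only loosely, was not removed by this. The calls that remain therefore do not argue against composition itself as the cause. For how much of the fold of the 3507 genes each accounts, library composition and a change in the endometrium (treatment, time, repeated sampling or the embryo cycle between the biopsies, none of them tested) cannot be told apart, since the share runs with the group. A difference in how the libraries of the 2 groups were made or sequenced was not tested and cannot be set apart from these.

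The second pattern is the smaller number of genes detected after treatment. A difference in the number of counts alone is argued against, since the difference at equal depth was -1837 genes with a standard error of 231. Thinning does not equalise other properties of the shallower libraries. At equal depth libraries 25 to 34 detected 14405.5 ± 760 genes and libraries 18 to 24 detected 15511 ± 492 (SD, n = 10 and 7), a gap that was not tested. Background reads from genomic DNA or unspliced RNA, varying between libraries, are a candidate explanation, because libraries with more reads outside genes also gave more of their gene counts to genes too low for testing within each group (before treatment r = 0.65 with adjusted p = 0.00759 and rho = 0.67 with adjusted p = 0.00799, after treatment r = 0.61 with adjusted p = 0.00344 and rho = 0.65 with adjusted p = 0.00799, permutation tests adjusted over the 4 relations given here, n = 17 each). Without the 2 libraries farthest from the median share, r was 0.65 (permutation p = 0.00953) and 0.49 (permutation p = 0.0452). The smaller rho was 0.652. This relation does not identify the source of those reads, since reads in 3′ ends that the annotation lacks also fall outside genes. The relation of the same share with the number of genes detected at equal depth was weaker before treatment (r = 0.51 with adjusted p = 0.0369 and rho = 0.59 with adjusted p = 0.0136) than after it (r = 0.71 with adjusted p = 0.00344 and rho = 0.71 with adjusted p = 0.0072), a difference that was not tested. Without the 2 farthest libraries it was 0.39 before treatment, which did not pass the test (permutation p = 0.149), and 0.67 after it (permutation p = 0.00732). The evidence for background reads is therefore less firm for the detected genes themselves. A change in the make-up of cell types was not tested and stays open, since the IDs could not be matched to marker genes.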

How the results depend on the processing

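Of 15 alternative settings for the count of 3507 genes, 12 stayed within 1.5 times of it (2944 to 4859 genes) and shared 79.5% to 97.8% of the 3507 calls in the same direction. The 3 that moved it were chosen after seeing the data. They are the share of reads outside genes as covariate (66 genes, 43 higher and 23 lower), that covariate with a pair block (3 genes), and leaving out libraries 25 to 34 (890 genes), which also removes 10 of 17 libraries. Without those 10, the median absolute log2 fold change of the 3507 genes was 0.42 with a standard error of 0.17, against 0.55 and 0.14 over all libraries, and the 4 gene IDs stayed past the threshold (log2 fold changes 1.32, 0.95, -0.82 and -0.67). The covariate raised the standard errors, since it runs with the group. DESeq2 called 3880 genes, 45.4% of them higher, and testing without a low-count filter called 4859, of which 36.3% were higher against 52.0% with the filter. Without the filter the median log2 fold change over all genes was -0.18. Leaving out each library in turn gave 3149 to 3865 genes. Of 196 alternative values for the 4 gene IDs, 0 changed sign and 6 lost the threshold, all under the covariate. The whole-transcriptome difference, the detected genes and the reads outside genes kept their direction and their side of the threshold under each of their alternatives. The spread kept its direction under 6 alternatives but did not pass the test without libraries 25 to 34 (difference 5.78, permutation p = 0.0757, and at equal depth 4.65, permutation p = 0.104), 2 settings chosen after seeing the data, with 7 libraries left after treatment. As a pair block, libraries n and n+17 called 3653 genes, 91.6% of the 3507 among them. The labels do not state this pairing, and over all tested genes 13 of 34 libraries correlated best with their own partner, where 2 would do so by chance. In genes with 2 levels before treatment it was 22 of 34 (178 genes), 24 (41 genes), 17 (14 genes) and 23 (8 genes), with a growing gap between the levels. The simulated fit recovered 46% of 1.5-fold changes, so changes of that size can be missed. The rate itself belongs to a simulation with 200 changed genes and does not carry over to the data. The settings listed for gene lists and stained-protein markers were not run because no gene ID could be matched to a symbol here, and mitochondrial genes could not be removed for the same reason.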

Other observations

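All tests in this part were chosen after the results were seen. Libraries numbered n and n+17 may come from the same mare, a hypothesis that the labels leave open. Over the 12613 tested genes, deviations from the group mean correlated by a mean of 0.109 between n and n+17, against -0.0066 for other pairings (one-sided permutation p = 4e-05), but only 8 of 17 pairs exceeded 0.1. The likeness was larger in genes that split the libraries from before treatment into 2 separate levels. In 178 genes with a gap of at least 1 log2 unit the mean correlation was 0.348, in 41 genes with a gap of 1.5 it was 0.492, in 14 genes with a gap of 2 it was 0.638 and in 8 genes with a gap of 2.5 it was 0.812 (permutation p = 1e-05 for each, the smallest the resamples can give). In these 8 genes the correlation of library 10 with library 27 was 0.387 and that of library 14 with library 31 was 0.189, the lowest of the 17, whereas library 10 with library 31 gave 0.909 and library 14 with library 27 gave 0.894. Over all genes these 4 correlations were 0.128, -0.014, 0.116 and -0.029, which does not favour either arrangement. A second exchange in the same 8 genes gave 0.785 for library 9 with library 34 and 0.720 for library 17 with library 26, against 0.501 and 0.638 for their own partners, but over all genes it went the other way (0.027 and -0.091 against 0.229 and 0.115). The 8 genes therefore do not identify partners by themselves, and no library was reassigned.

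The change between the groups may run along an axis on which biopsies of 1 group also differ. Across the 12613 genes, which are not independent, the slope of log2 CPM on the share of reads outside genes among the 17 libraries from before treatment correlated with the difference between the groups by r = -0.381. Of 100 draws including the real one, 4 were as low and 12 as large in either direction, with permuted values from -0.414 to 0.566, so the test leaves this open. Among the 17 libraries from after treatment r was -0.635, and 1 of 100 draws, the real one, was as low. In fits on that share within a group, 15 genes were called before treatment and 722 after it (edgeR, adjusted p below 0.05), with 2218 and 2498 of 12613 at an unadjusted p below 0.05. The difference between the groups was not tested.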
